A study of Mus musculus with 3 samples.

How the data were processed

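CD8+ T cells of 3 populations were profiled with 1 Affymetrix array each. Per the labels' protocols, the cells came from the spleen and lymph nodes of C57BL/6 mice that carry a green fluorescent protein reporter of the chemokine receptor CXCR3, were stained for surface markers that include CD44 and CD8, and were sorted by flow cytometry. Total RNA was taken from about 3 to 5 mice, per the labels, and biotin-labelled. The authors deposited log2 expression values, which were made with RMA in Affymetrix Expression Console, per the submitters' processing notes, with no version given in the sources used here. RMA corrects background, sets the arrays to a common distribution and summarises the probes of each probe set by median polish.

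The deposited log2 table held 12417 probe sets in each of the 3 arrays. The highest value of each probe set was at least 7.00002, so probe sets below 7 on all arrays were not analysed here, and a gene that is not listed has no value rather than a value of 0. The platform annotation paired 10576 probe sets with 1 gene symbol, 1108 with several symbols and 733 with none. Only the first kind was used to name genes. Values of the 273 genes with several probe sets were averaged on the log2 scale, which gave 10191 genes. RNA classes and gene symbols were checked against a RefSeq gene table of the mouse assembly GRCm38.p6, used for names and classes only. The sources used here name no genome build for the array, so no coordinates are printed. The number of arrays limits the precision.

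With 1 array per group no test between groups, no standard error and no p-value could be computed, and no difference has a replicate check. Differences of log2 values were compared by a rule of size: a gene counted as higher or lower when its values differed by at least 1 on the log2 scale (2-fold) and its higher value was at or above the median of that array over all genes. The 3 comparisons were CXCR3+ innate minus naive, CXCR3- innate minus naive and CXCR3+ innate minus CXCR3- innate. For 30 gene lists, the median difference of the measured members was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these 3 arrays. Of 541 distinct listed genes, 302 were measured. The overlap of the 2 comparisons with naive cells was set beside 200 simulated sets of 3 arrays without any effect that shared the naive array, and so was the position of CXCR3- innate values between the other arrays, a simulation chosen after the data were seen. Each difference was also divided by the robust SD of the 500 genes nearest in level. That SD was 0.000 at some levels in every comparison because many values were equal between arrays, so these ratios were not used to rank genes.

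The genes to name were set by rule: the sort genes, up to 10 genes with the largest difference in each direction among those passing the size rule, up to 4 members with the largest absolute difference in each described list, and listed transcription factors and receptors that passed between the innate populations. By their symbols, predicted genes, olfactory and vomeronasal receptors, microRNAs, small nucleolar RNAs, small nuclear RNAs, histone clusters, antigen receptor segments and genes whose probe sets carry several symbols were counted and not named. Small RNAs whose symbols do not show their class, such as the small nucleolar RNA AF357355 and the Scarna genes, were not left out by this rule. The comparisons, lists, size rule, naming rule and most alternatives were chosen before the data were examined. The classes of RNA in the RefSeq table and the families picked out by gene symbol were chosen afterwards. So were the counts without small nucleolar, Cajal body and nuclear RNAs and those of genes with a value below the receptor gene median.

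The alternatives were no filter on dim genes, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, an added requirement of 3 local robust SDs, quantile normalization, cyclic loess, centring on the median, an offset of 16 added on the linear scale, the probe set with the highest mean for each gene, every probe set by itself, and list medians over only the members above the filter on dim genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1. The size rule was tested on simulated data of 10191 genes for each comparison. Before the filter on dim genes, it found 100.0% of the genes with a true difference of 1.5 for CXCR3+ innate minus naive, 100.0% for CXCR3- innate minus naive and 99.0% for the comparison of both innate populations. With the filter it found 70.0%, 74.0% and 79.0%. It found 0.0% of genes with a true difference of 0.5 in each comparison. Apart from the losses to the filter, these shares follow from the threshold of 1 and the small simulated noise. The simulated noise was set from the difference between the innate arrays and holds no spread between mice.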

Results

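Gene expression was measured in CXCR3+ innate, CXCR3- innate and naive CD8+ T cells sorted from naive CXCR3 reporter mice kept in pathogen-free conditions. Innate here is the submitters' name for the populations set apart from naive CD8+ T cells. Each population was represented by 1 array. Values were log2 RMA expression values, and the array medians over 12417 probe sets were 7.70 in CXCR3+ innate cells, 7.68 in CXCR3- innate cells and 7.71 in naive cells. Because no population was replicated, no difference below could be compared with a spread between replicates, and higher and lower refer to the values on these 3 arrays. Equal values were frequent: 34.19% of probe sets had the same value on all 3 arrays. A difference of exactly 0 in a gene therefore does not show that its expression was the same.

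The sort genes were examined first. Cxcr3 read 7.97 in CXCR3+ innate, 7.82 in CXCR3- innate and 7.57 in naive cells, around 7.727, the median level of the olfactory and vomeronasal receptor genes that passed the filter of this table. Cd44, the adhesion receptor raised on antigen-experienced and memory-phenotype T cells, read 8.30, 7.88 and 7.24 in the same order. The CD8 coreceptor genes were high on every array, with Cd8a at 10.14, 9.77 and 10.43 and Cd8b1 at 11.31, 11.29 and 11.54. The list median of the 4 measured sort genes was 0.08 for CXCR3+ innate minus naive, -0.01 for CXCR3- innate minus naive and 0.26 for CXCR3+ innate minus CXCR3- innate. Cxcr3 itself differed by only 0.15 between the innate populations. The median of -0.01 was above 0 after quantile normalization, cyclic loess and centring on the median.

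The first comparison asked how CXCR3+ innate cells differ from naive CD8+ T cells. The chemokine gene Ccl5 had the largest difference, at 12.49 in CXCR3+ innate and 7.83 in naive cells, which is 25.2-fold. Ly6c2, a surface antigen of memory-phenotype CD8+ T cells, was 6.00-fold higher. Klrc1, which encodes the natural killer receptor NKG2A, was 3.75-fold higher, and Slamf7 was 2.81-fold higher. Tbx21, encoding the transcription factor T-bet, was 2.48-fold higher. On the other side, Ifngr2, a chain of the interferon gamma receptor, was 4.46-fold lower and Itgae, encoding the integrin CD103, was 3.78-fold lower. By the size rule 14 genes were higher and 10 were lower among 10191 genes. The other named genes that were higher were Xcl1, a chemokine, by 1.34 on the log2 scale, Il18rap, a chain of the interleukin-18 receptor, by 1.31, Plek by 1.17, Bhlhe40 by 1.12 and Cd44 by 1.06. Il2rb, the receptor chain shared by interleukin-2 and interleukin-15, passed narrowly at 1.003. The other named genes that were lower were Trib2 at -1.28, Rab3ip at -1.25, Igfbp4 at -1.21, Als2cl and Cpm at -1.09, Cd226 at -1.06 and Cep97 at -1.05. With the linear offset, Cd44, Il2rb and Cep97 did not reach 2-fold. In 9 of the 14 higher and 5 of the 10 lower genes, Klrc1, Slamf7, Tbx21 and Itgae among them, the lower of both values lay below 7.727, the median level of those receptor genes. These are other probes, selected by the same filter, so that level is not the background of the named genes.

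Genes typical of naive T cells were lower as a group in CXCR3+ innate cells. Of 16 measured members, 2 were at least 2-fold lower, none was 2-fold higher, and 15 had a difference below 0. The list median was -0.44, at percentile 0.00 of the random lists. The largest differences were those of Igfbp4 and Als2cl, given above, Dapl1 at -0.89 and Ccr7, the lymph node homing receptor, at -0.81. Cytotoxic granule and death ligand genes had a median of 0.38, at percentile 100, but none of the 13 measured members reached 2-fold. Fasl differed by 0.92, Serpinb6b by 0.78, Anxa2 by 0.74 and Ctsw by 0.64, whereas Prf1, encoding perforin, had an equal value on both arrays. Chemokines had a median of 0.55 over 6 members, at percentile 100, with Ccl5 and Xcl1 at least 2-fold higher, Ccl4 at 0.56 and Ccl3 at 0.54. Over only the members above the filter on dim genes the chemokine median was 0.95. Natural killer receptors had a median of 0.18 over 8 members, at percentile 99.99. Klrc1 and Slamf7 passed the size rule, Klra9 differed by 1.04 but stayed below the level filter, and Cd160 differed by 0.22.

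Effector and memory transcription factors held members on both sides in CXCR3+ innate minus naive. Tbx21 and Bhlhe40 were at least 2-fold higher and Eomes differed by 0.85, Id2 differed by -0.91, 6 of the 14 measured members were equal on both arrays, and the list median was 0.00. Cytokine receptors and JAK-STAT genes likewise differed in direction, with Il18rap and Il2rb higher, Ifngr2 lower, Il6st at -0.71 and a median of 0.00 over 25 genes. Among integrin and adhesion genes, Ly6c2 was higher, Itgae was lower, Itga4 differed by -0.77 and Itgb1 by 0.68. The median of that list was 0.00 over 13 genes. Chemoattractant receptors had a median of 0.17 over 7 genes, at percentile 99.95. Cxcr5, the receptor for the B cell follicle chemokine, differed by 0.78, Cxcr4 by 0.34, Cx3cr1 by 0.24 and S1pr5 by 0.17. No member of that list passed the size rule.

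The second comparison set CXCR3- innate cells against naive cells. Ccl5 was again the gene with the largest positive difference, at 8.10-fold higher, and Ly6c2 was 2.14-fold higher. No other gene passed the size rule upward, so 2 genes were higher and 23 were lower. Itgae at -1.03 and Ifngr2 at -1.01 were lower here too, but passed narrowly. Neither passed after quantile normalization, centring on the median or the linear offset, and Ifngr2 did not after cyclic loess. Most of the lower genes were of another kind: 12 of the 23 were small nucleolar, small Cajal body or small nuclear RNAs, which guide or carry out RNA modification and splicing. Scarna6 differed by -1.44, Scarna17 by -1.13 and Scarna2 by -1.07. Terc, the RNA component of telomerase, differed by -1.23. Rny3, a small cytoplasmic RNA, and Zfas1, a host transcript of small nucleolar RNAs, both differed by -1.05. The remaining named genes were Cox7b of cytochrome c oxidase at -1.15, the chaperonin subunit Cct6a and the ATP synthase subunit Atp5md at -1.04, and the proteasome subunit Psmb1 at -1.03. Quantile normalization left 2 genes higher and 9 lower, which moved the share of higher calls from 8.0% to 18.2%. Without the small nucleolar, Cajal body and nuclear RNAs and the ribosomal protein genes, a count added after the data were seen, 2 genes were higher and 10 were lower.

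The gene lists gave a mixed picture of the CXCR3- innate cells. Naive T cell genes had a median of -0.44, at percentile 0.09, with no member past 2-fold. Igfbp4 was at -0.83, Lef1, a transcription factor of naive and memory T cells, at -0.72, Als2cl at -0.64 and S1pr1, the receptor for lymph node exit, at -0.53. Families picked after the data were seen had medians as low in this comparison, each at percentile 0.00. They were -0.49 for small nucleolar RNAs and -0.52 for chaperonin Cct subunits. Chemokines had a median of 0.38, at percentile 100, with Xcl1 at 0.60, Ccl3 at 0.47 and Ccl4 at 0.29. Natural killer receptors had a median of 0.23, at percentile 100, with Slamf7 at 0.83, Klrc1 at 0.57, Klrd1 at -0.50 and Ncr1 at 0.24. Chemoattractant receptors had a median of 0.17, at percentile 100, with Cxcr5 at 0.60. Cytotoxic granule and death ligand genes had a median of 0.00, with 6 members above 0 and 6 below, and one of -0.12 over only the members above the filter on dim genes. Ctsw was at -0.45, Serpinb6b at 0.35, Cst7 at -0.34 and Fasl at 0.30. Cytosolic ribosomal protein genes were lower as a group, with 26 of 29 members below 0, a median of -0.39 at percentile 0.00 and 1 member, Rps19, past 2-fold at -1.02. Rps19 no longer passed after centring on the median. Rpl14 was at -0.92, Rpl7 at -0.90 and Rpl8 at -0.86. The same list had a median of -0.04 in CXCR3+ innate minus naive. T cell receptor signalling genes had a median of -0.19, at percentile 34.33, with Cd3g at -0.93 and Cd3d at -0.52, and one of -0.0996 after quantile normalization. Integrin and adhesion genes had a median of -0.10, with Ly6c2 higher and Itgae lower, and cytokine receptors one of -0.08, with Il21r at -0.61. Effector and memory transcription factors had a median of 0.00, with Id2 at -0.95, Eomes at 0.71, Tbx21 at 0.62 and Bhlhe40 at 0.56.

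**Figure D1:**
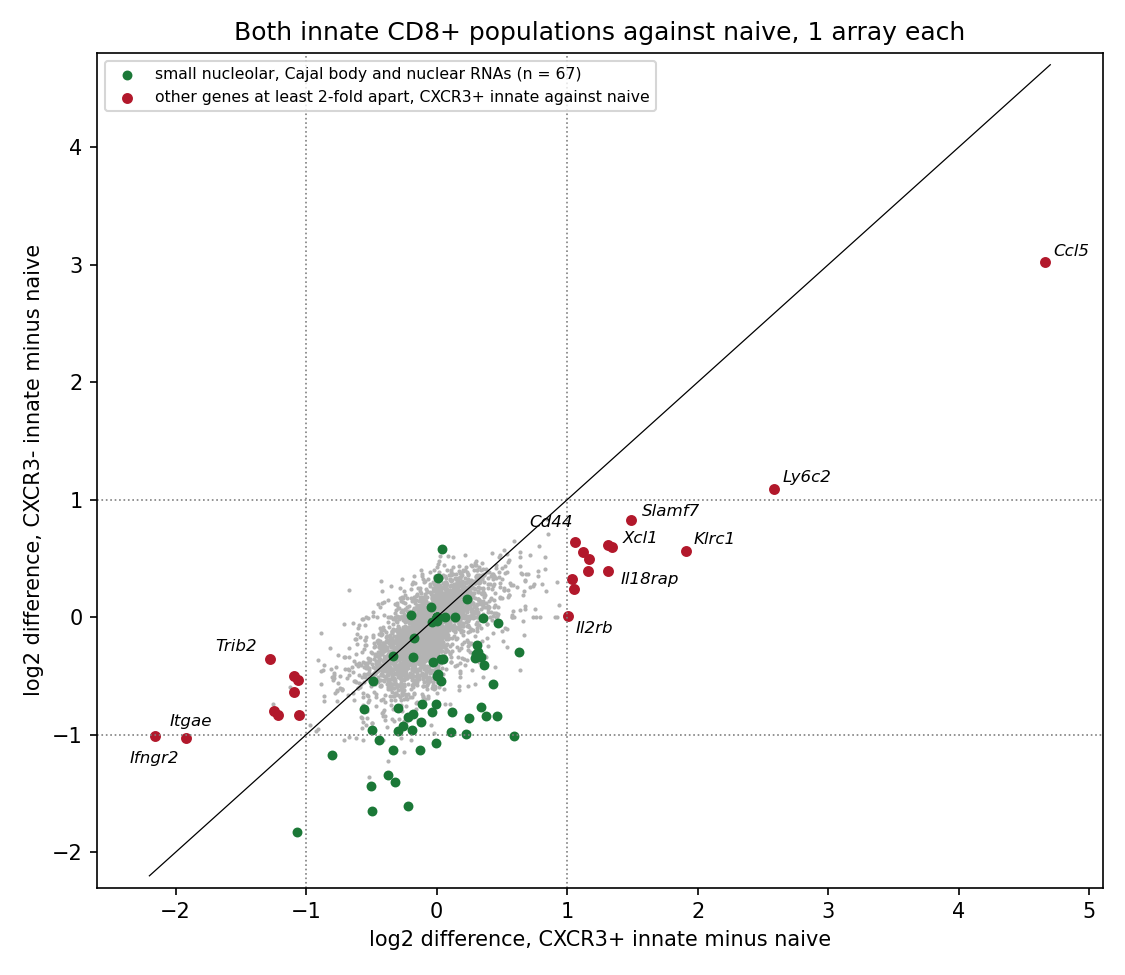
Log2 difference of each of 10191 genes from naive cells in CXCR3+ innate (x axis) and CXCR3- innate cells (y axis), 1 array each, with dotted lines at a difference of 1 in either direction and a solid line of equality. Ccl5 lies at 4.66 and 3.02, and the small nucleolar, Cajal body and nuclear RNAs (n = 67) lie mostly below the line of equality.

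The overlap of these comparisons was examined next. Ccl5 and Ly6c2 were at least 2-fold higher in both innate populations than in naive cells, and 3 genes were lower in both, Ifngr2, Itgae and the small nucleolar RNA Snora16a, which the naming rule leaves out and which is named here after its values were seen. After quantile normalization or centring on the median 1 gene was lower in both, since Itgae and Ifngr2 no longer passed. Arrays simulated without any effect that shared the naive array gave a mean overlap of 0.0000 genes in each direction with the robust local SD, and of 0.01 upward and 0.005 downward with the plain local SD. Between the innate arrays, which set this noise, the robust local SD had a median of 0.000 and a highest value of 0.209. At that noise a 2-fold difference was almost out of reach, so the 0.0000 is no benchmark for the observed overlap. All 14 genes higher in CXCR3+ innate than in naive cells had a CXCR3- innate value strictly between the other arrays, at a median of 42.4% of the log2 difference. Of the 10 lower genes, 9 lay between, and the median share over all 10 was 56.0%. Arrays simulated without any effect, with genes chosen by the largest CXCR3+ innate minus naive differences, put a mean of 11.5 of 14 and 8.6 of 10 genes between, at mean shares of 49.8% and 50.5%. Across genes, which are not independent replicates, the differences from naive cells correlated at r = 0.66. Both differences share the naive array, and arrays simulated without any effect gave r = 0.50. That value follows from giving all 3 simulated arrays the same noise. With more noise on the naive array it would be higher, so it cannot decide whether the observed r exceeds noise. The covariance was 0.0219, against a simulated 0.0018 with the robust local SD and 0.0106 with the plain local SD, the latter chosen after the data were seen. The simulated value with the robust local SD is low because that SD was 0.000 at many levels. The part of the covariance that comes from the shared array could not be measured, since that array could not be split.

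The third comparison set the innate populations against each other. CXCR3+ innate cells had higher values of Ccl5, by 3.12-fold, of Ly6c2, by 2.81-fold, and of Klrc1, by 2.53-fold. Ctsw, which encodes the protease cathepsin W, was 2.13-fold higher. Ifngr2 was 2.22-fold lower and was the only gene that passed the size rule downward. In all, 15 genes were higher and 1 was lower, and 11 of the 15 were small nucleolar, Cajal body or nuclear RNAs. Among them were Scarna2, at 1.07, and the small nucleolar RNA AF357355, at 1.22. Without small nucleolar, Cajal body and nuclear RNAs and ribosomal protein genes, 4 genes were higher and 1 was lower. Klrc1 and Ifngr2 were the listed receptors that passed, and no listed transcription factor did. Il2rb had a difference of 0.995, just under the rule, while its CXCR3- innate value was 0.01 above naive.

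Cytotoxic granule and death ligand genes had a median of 0.19 between the innate populations, at percentile 99.92, and of 0.00 in CXCR3- innate minus naive. In the same comparison of the innate populations, families picked after the data were seen also had medians above 0, each at percentile 100. They were 0.56 for small nucleolar RNAs, 0.48 for chaperonin Cct subunits and 0.15 for oxidative phosphorylation subunits. Translation factors and some of their regulators, picked by Eif and Eef symbols, had one of 0.17. Of 13 cytotoxic members, 11 were above 0 and 2 were equal, with Cst7 at 0.72, Fasl at 0.62 and Nkg7 at 0.56 after Ctsw. Naive T cell genes had a median of -0.22, at percentile 0.00, with Als2cl at -0.45, Dapl1 at -0.43, Il7r at 0.40 and Igfbp4 at -0.38. Natural killer receptors had a median of 0.22, at percentile 99.97, with Klra9 at 0.81, Slamf7 at 0.66 and Klrd1 at 0.36. Chemokines had a median of 0.17, at percentile 99.31, with Xcl1 at 0.74. Over only the members above the filter on dim genes, the medians were 0.43 for cytotoxic granule and death ligand genes, 0.36 for natural killer receptors and 0.51 for chemokines. Among cytokine receptors Il18rap differed by 0.92 and Il18r1 by 0.69, and the list median was 0.00. Effector and memory transcription factors had a median of 0.02, at percentile 98.91, with Tbx21 at 0.70, Bhlhe40 at 0.56, Nfil3 at 0.23 and Hopx at 0.21. This median was -0.0003 after quantile normalization and 0.14 over only the members above the filter on dim genes. Integrin and adhesion genes had a median of 0.16, at percentile 99.18, with Itgae at -0.89 and Itgb1 at 0.61. Cytosolic ribosomal protein genes had a median of 0.33, at percentile 100, with Rpl14 at 0.87 and Rpl38 at 0.81. Chemoattractant receptors had a median of 0.00, with Cxcr4 at 0.55.

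**Figure D2:**
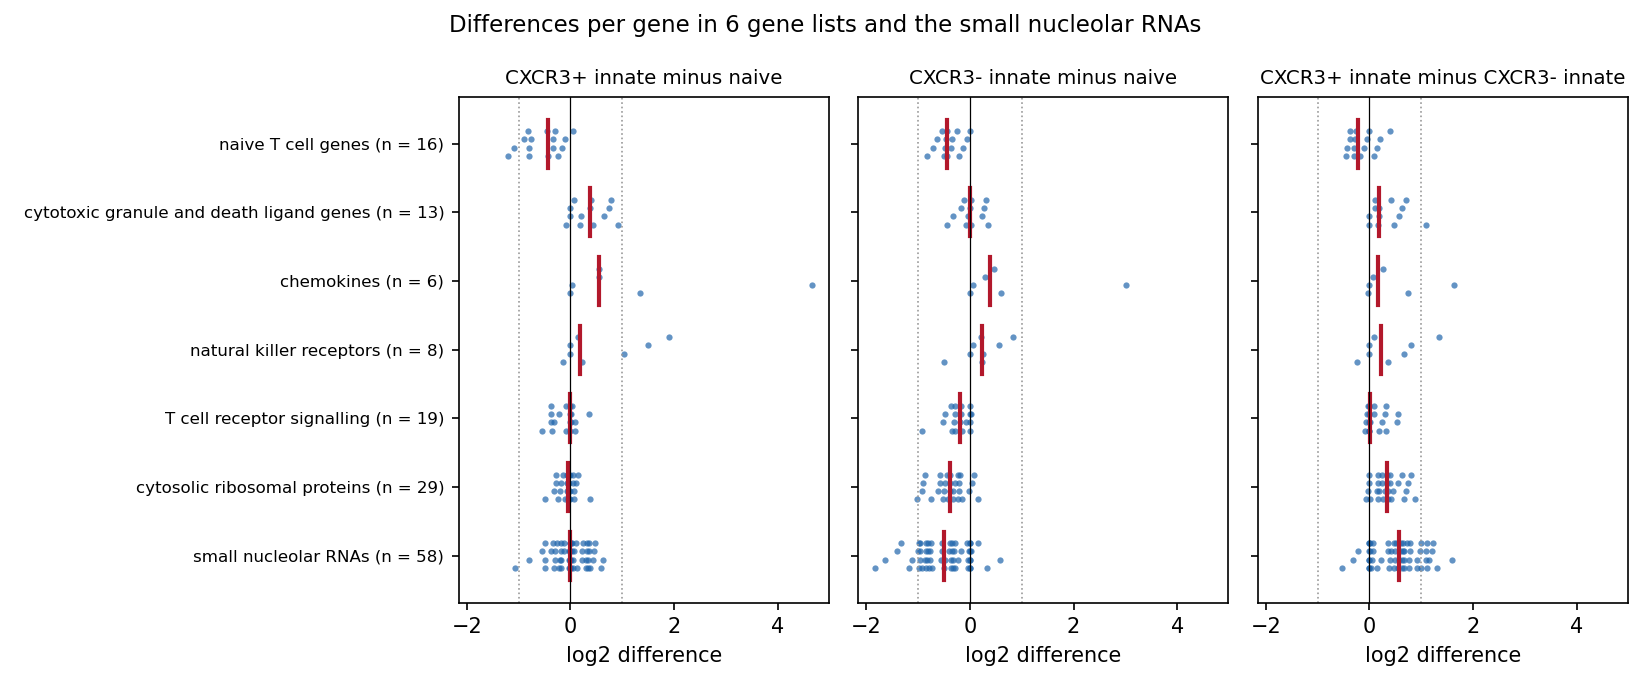
Log2 difference of each measured gene (points) in 6 gene lists and in the small nucleolar RNAs, with the list median as a red bar, for the 3 comparisons of 1 array each. Dotted lines mark a difference of 1 in either direction. The ribosomal protein median is -0.39 in CXCR3- innate minus naive and -0.04 in CXCR3+ innate minus naive.

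Lists of other programmes showed few differences among their measured members. Measured were 13 of 33 cell cycle, 16 of 34 interferon-stimulated, 11 of 22 survival and 9 of 16 fatty acid oxidation genes. So were 6 of 16 cytokines and 7 of 18 cholesterol synthesis genes, and coverage was higher in the other lists. In CXCR3+ innate minus naive, 10 interferon-stimulated and 6 cell cycle genes were exactly equal, so a median of 0.00 does not show an unchanged programme. For CXCR3+ innate minus naive, CXCR3- innate minus naive and CXCR3+ innate minus CXCR3- innate in that order, the medians were 0.00, 0.00 and 0.00 for cell cycle, interferon-stimulated, survival and fatty acid oxidation genes. They were 0.01, 0.01 and 0.03 for cytokines, 0.00, -0.06 and 0.07 for immediate early and stress genes, 0.00, 0.00 and 0.04 for glycolysis, -0.03, -0.03 and 0.00 for cholesterol synthesis, and -0.0015, 0.00 and 0.00 for activation and inhibitory receptors. For T cell receptor signalling the medians of CXCR3+ innate minus naive and of the innate populations were 0.00 and 0.0029. Several medians this close to 0 took the other sign under another scaling, and the cytokine median of CXCR3- innate minus naive differed in sign from the mean of -0.0152. No member passed the size rule except Cd226 among the inhibitory and activation receptors. Aurkb, a mitotic kinase, differed by 0.49 in CXCR3+ innate minus naive, and the interferon-induced Gbp4 by -0.76. Jun differed by -0.72, Mcl1 by -0.52 and the lactate transporter gene Slc16a1 by -0.56. Tigit differed by 0.64.

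Markers of other cell types were mostly not listed among the measured genes. Only 3 of 20 B cell genes, 3 of 7 plasma cell genes, 3 of 7 CD4 and regulatory T cell genes and 2 of 10 gamma-delta T cell genes had values. In the order used above, the medians were 0.00, 0.02 and -0.02 for B cells, -0.0049, -0.0049 and 0.00 for plasma cells, and 0.00, 0.00 and 0.00 for CD4 T cells, natural killer cells, erythroid cells and platelets, and stroma. They were 0.00, 0.01 and 0.00 for myeloid cells, 0.04, 0.15 and -0.04 for granulocytes and -0.02, -0.02 and 0.00 for 3 Y-linked genes. The B cell median of CXCR3- innate minus naive differed in sign from its mean of -0.0548. Pecam1, a listed endothelial gene that T cells also express, differed by -0.87 in CXCR3+ innate minus naive. The granulocyte median in CXCR3- innate minus naive stood at percentile 99.53 over 4 genes, with S100a9 at 8.31 against 8.09 in naive cells. Of the gamma-delta T cell genes, Cd163l1 differed by 0.45 in CXCR3+ innate minus naive and Sox13 was equal, and with 2 genes no median was taken. Among the 5 natural killer cell genes, Eomes differed by 0.85 in CXCR3+ innate minus naive and the other 4 were equal on both arrays. Eomes and Prf1 are also expressed by CD8+ T cells.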

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

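The tests of brighter short-span genes, microRNA hairpins, receptor genes and ribosome production were chosen after the result was seen, as was the minimum of 0.25 used in the next paragraph.

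In 5 named genes the value was at least 0.25 above naive on the CXCR3+ innate array and at least 0.25 below naive on the CXCR3- innate array, and with 1 array per population these opposite directions were not tested. The CXCR3+ innate minus CXCR3- innate difference was 1.22 for AF357355, 1.09 for Ctsw, 0.72 for Cst7, 0.71 for Cd7 and 0.70 for Rpl32. Of 168 named genes, 22 lay on opposite sides of naive by any amount, and over all genes 601 did against 4242 on the same side. Over all genes 26 lay at least 0.25 away on opposite sides, 11 of them small nucleolar, Cajal body or nuclear RNAs, with 23 above naive on the CXCR3+ innate array and 3 below.

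Among the 1841 probe sets with several gene symbols or none, which the gene comparisons left out, 2 were at least 2-fold higher and 1 lower in CXCR3+ innate than in naive cells, and 0 were higher and 8 lower in CXCR3- innate than in naive cells; between the innate populations 6 were higher and 2 lower in CXCR3+ innate cells.

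The lower small nucleolar RNAs and ribosomal protein genes of the CXCR3- innate array may be technical or biological, and a trend with level is argued against as the whole cause, since cyclic loess left the small nucleolar RNA median at -0.4685. Poorer recovery was tested in 3 ways, each later one put in after the one before had been seen, and all 3 met the bounds written against it: the median of short-span protein-coding genes (under 5 kb), with its bound set beforehand, was 0.0000, the mean of the brighter ones was -0.0280 against -0.1047 in random lists, and the median of brighter microRNA hairpins, close in level to the small nucleolar RNAs, was 0.0750 with a middle range of 0.0000 to 0.2225. The hairpins would argue against poorer recovery of small RNAs as a whole only if their probes read hairpins, which was not tested. Olfactory and vomeronasal receptor genes, which stand for background here, had a middle range of 0.0000 to 0.1107, also not below 0. The hairpins alone therefore do not decide. The short-span values are left undecided for reasons found afterwards: 615 of 1553 were exactly 0 and fix that median. Of the brighter set, 37.5% are receptor, keratin and defensin genes not expected in T cells. Lower signal over background was tested last, on olfactory and vomeronasal receptor genes: the median of 0.0000 met the bound against it, yet 203 of 530 values were exactly 0 and fix it, and the mean of 0.0542, with 254 genes above 0 and 73 below, was put in its place for a time after it had been seen, was taken back and decides nothing. Poorer recovery of small RNAs or short mRNAs, lower signal and lower ribosome production (ribosomal protein median -0.3877) cannot be told apart with 1 array of each population.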

How the results depend on the processing

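The counts without small nucleolar, Cajal body and nuclear RNAs and ribosomal protein genes were added after the data were seen. The other alternatives were planned. Against naive cells, 14 genes were higher and 10 lower in CXCR3+ innate cells, and 2 higher and 23 lower in CXCR3- innate cells; between the innate populations 15 were higher and 1 lower. At 1.5-fold these counts were 51, 71, 10, 163, 102 and 8, and at 3-fold 3, 2, 1, 3, 2 and 0; by construction a lower threshold admits more genes. The genes higher and lower in both innate populations (2 and 3) were 9 and 28 at 1.5-fold, and 1 and 0 at 3-fold. The 23 lower genes of CXCR3- innate cells were 9 after quantile normalization, 15 with the linear offset and 35 with every probe set by itself. Without small nucleolar, Cajal body and nuclear RNAs and ribosomal protein genes they were 10, with Terc and Rny3 still counted. Leaving these out also left 4 of the 15 genes between the innate populations. The cause of the changes with quantile normalization and the offset was not tested. With every probe set by itself the 1 lower gene between the innate populations became 3. Probe sets without a single gene symbol make up 2 of those 3 and 8 of the 35; the other 27 are 24 of genes that had passed and 3 of genes that had not. The 3 genes lower in both became 1 after quantile normalization and 1 after centring, as Itgae and Ifngr2 no longer reached 2-fold. Of 87 counts and correlations, 63 stayed within 1.5 times and 24 moved; 6 of the 63 come from the local SD requirement, which could remove no gene, since the highest local robust SD was 0.319. Of 495 list medians under alternatives, 460 shifted from the deposited median by no more than the random lists spread to either side. Such a median can itself still lie outside the random lists. Another 34 shifted by more, and 1, from a list beyond the central range of its random lists, reversed. This was the transcription factor median between the innate populations, at -0.0003 after quantile normalization. The cause of the reversal was not tested. A further 19 changed sign in lists within that range, all with a deposited median within 0.0637 of 0. Of 1765 values of named genes, 1760 shifted by no more than the local SD, 5 shifted by more and none changed direction after passing the size rule. The background correction could not be redone, and a slide block was not run, with 1 array per group. No paired analysis was possible because each group holds 1 array. Signal close to background limits genes near the lowest value of the table.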

Other observations

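The tests on a library deposited more than once, on a mixture with lower signal and on noise of the shared naive array and the mixtures simulated with noise were chosen after the result was seen, as were the gene families described first.

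Some families of housekeeping genes, picked by symbol, were lower on the CXCR3- innate array under every scaling tried. Their medians include Cct6a, Cox7b, Atp5md and Psmb1, already named as lower in CXCR3- innate minus naive, so they are no separate evidence. The glycolysis list, set beforehand, had a median of 0.00 in that comparison, with 6 of 13 members exactly equal. In CXCR3- innate minus naive, 7 measured subunits of the chaperonin Cct, which folds actin and tubulin, had a median of -0.52, and all 7 were below 0. The 52 oxidative phosphorylation subunits had a median of -0.22, with 38 below 0 and 2 above, and one of -0.1077 after quantile normalization. The 47 genes with Eif or Eef symbols, called translation factors here, had a median of -0.22. They include regulators of these factors, such as Eif2ak3 and Eif4ebp1. The 33 proteasome subunits had a median of -0.105. In CXCR3+ innate minus naive the median was -0.06 for Cct subunits and -0.05 for translation factors (-0.0085 and -0.0036 after quantile normalization). It was -0.0038 for oxidative phosphorylation and -0.0069 for the proteasome, and both were above 0 after centring on the median (0.0135 and 0.0104). The 58 small nucleolar RNAs had a median of -0.49 in CXCR3- innate minus naive and 0.00 in CXCR3+ innate minus naive. MicroRNA hairpins differed in direction, with a median of 0.06 over 139 in CXCR3- innate minus naive and 0.1019 after cyclic loess.

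Exactly equal values made up 45.06% of probe sets for CXCR3+ innate and naive cells, 41.98% for CXCR3- innate and naive cells and 48.03% for the innate populations. A library deposited more than once is argued against, since the highest of these shares was 1.14 times the lowest. Median polish over 3 arrays may produce them: simulated probe sets of 10 to 31 probes with no difference gave equal values in 32.4% to 90.5% of cases, under an assumed probe noise SD of 0.3. In that simulation with 21 probes a true difference of 0.3 had a median estimate of 0.155 and one of 1.0 had 0.877, so small differences on these arrays may be understated.

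CXCR3- innate values lay between those of the other arrays for 14 of 14 higher and 9 of 10 lower genes that separate CXCR3+ innate from naive cells. Genes chosen by a large CXCR3+ innate minus naive difference tend to lie between even without any effect. Arrays simulated without any effect put a mean of 11.5 of 14 and 8.6 of 10 such genes between, at a mean share of 49.8% and 50.5% of the log2 difference, and the observed shares of 42.4% and 56.0% lie within the simulated ranges, although at most 4 simulated genes passed the size rule and the observed gap in linear share of 41.1 points lies just above the simulated range of -16.4 to 39.9 (mean 12.1, highest 59.0). A plain mixture of naive and CXCR3+ innate RNA is argued against by the bound set before the shares were seen: the median linear share was 27.2% for the higher and 68.3% for the lower genes (27.5% and 67.4% after cyclic loess), 41.1 percentage points apart with middle ranges that did not overlap, whereas simulated mixtures with array noise were at most 14.6 points apart with the genes fixed and 38.8 with the genes chosen anew, and arrays without any effect reached more, as given above. A further setting was added only after that result: with the CXCR3- innate values raised by the ribosomal protein shift, itself taken from this array, the shares were 59.1% and 44.0%, a gap of -15.1 points with overlapping middle ranges. Arrays without any effect gave a mean of 0.5 and at most 4 genes past the size rule, against 24 observed. At the simulated noise a 2-fold difference was seldom reached, so these counts cannot decide whether noise is the only source of the differences. The simulated noise followed a normal distribution, whereas 49.0% of the gene differences between the innate arrays were exactly 0. That noise was set from the innate arrays, so noise particular to the naive array was not measured. Noise of the shared array, a mixture at lower signal and an intermediate cell state cannot be told apart for the position between.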
